A study of Mus musculus with 9 samples.

How the data were processed

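RNA sequencing libraries of 9 mouse cell cultures were analysed from the deposited gene counts. Per the labels, NSC (cultures 1, 3 and 5) are wild-type neural stem cells of the subventricular zone, LTR (1 to 3) carry lgT/Ras, and NF1 (1 to 3) carry Nf1 loss, shp53 and CDK4. Cultures were kept for up to 10 passages, RNA was purified with RNeasy Plus and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The deposited values are raw counts per gene, and the submitters' processing notes name STAR 2.5.2a, HTSeq, DESeq2 1.8.2, GRCm38 and mm10 without further settings. The annotation release, the counting mode and the strand setting are not given in the sources used here. The kit does not keep the strand, so counts of genes that overlap another gene, antisense partners included, are uncertain.

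The table held 47729 genes, of which 47224 identifiers are in GENCODE M21 (GRCm38), the source of coordinates and GC content, and 136 symbols occur more than once. Genes were analysed by identifier. Total counts ran from 28600479 (LTR 2) to 57231024 (NSC 3). All value columns were used, and chi-square per degree of freedom between libraries of a group ran from 14.5 to 436.3, so none is a copy of another.

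Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. One model of the 3 groups was fitted to all 9 libraries after TMM scaling and filterByExpr (minimum count 10), which left 15696 genes. Each pair of groups was compared by the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. A further count asked for a fold change of at least 2. The SE of a log2 fold change was derived from the F statistic, and fitted fold changes carry a prior count of 0.125. CPM are TMM-scaled. The p-values measure spread between the 3 cultures of a group. The sample titles tell these cultures apart only by number, so whether they were transformed separately is not known. Where a group had no count, a fold is given as at least the ratio to a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% counting interval.

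The 29 gene lists were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were Eph receptors and ephrins, other guidance cues, cytokinesis, G1/S genes, G2/M genes, p53 targets, cyclin D with INK4 and RB genes, MAPK output genes, 5 lists of neural stem cell, astrocyte, oligodendrocyte lineage, neuronal and ependymal markers, 3 lists of microglia and myeloid, endothelial, and mural cell and fibroblast markers, mesenchymal glioma genes, EMT genes, integrins and basement membrane, matrix proteases and inhibitors, Notch pathway, interferon-stimulated genes, MHC class I presentation, glycolysis and hypoxia, cholesterol synthesis, Hox genes, imprinted genes, immediate early and heat shock genes, and mitochondrially encoded mRNAs. Members with too few counts were not tested, among them 29 Hox genes, 11 microglia and myeloid markers, 8 ependymal and 8 mural cell and fibroblast markers. Calls shared by both tumour groups were set against independent lists of their sizes and against 20 simulations of unchanged groups (seed 20240). These drew all 9 libraries, NSC included, gene by gene at the NSC means. Both simulated tumour groups were compared with the same simulated NSC libraries.

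Genes were named by a rule: the genes of the labels with Hras and Nras, every measured Eph receptor and ephrin, and the 6 largest increases and decreases among genes past the threshold. Those had to change at least 2-fold, reach 8 CPM in the higher group, show no overlap between libraries and carry an established symbol. The rule also named up to 4 members of each list with the smallest adjusted p, the most abundant members that did not pass, 5 genes per direction that changed in both tumour groups, genes called in opposite directions, and Xist with 4 Y-linked genes. Genes outside the rule are marked as chosen after the values were seen. The tests, lists, naming rule and all alternatives except 3 were chosen before the data were examined.

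Alternatives were DESeq2 1.42.0 (Wald test), limma-voom, scaling by DESeq2 size factors, upper quartile or library totals, no filter, a filter of 10 CPM in 3 libraries, a fit of only the 6 libraries compared, the replicate number as a block, each library left out in turn, a test against a 2-fold threshold (glmTreat), and for lists ranks and fry. The 3 chosen after seeing the data left out both NF1 2 and NSC 3, or took out each library's GC trend without centring and with centring on its median, the centring after the uncentred version was seen. GC values were known for 15654 tested genes.

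Each comparison was tested on simulated data with 200 changed genes. Of genes changed 4-fold, 50% were recovered for LTR against NSC, 65% for NF1 against NSC and 56% for NF1 against LTR, and of genes changed 2-fold 4%, 3% and 4%. False calls numbered 4 of 58, 7 of 75 and 2 of 62, on 15316, 15301 and 15210 genes. The raised list was called in each comparison, with 1 other list in NF1 against LTR. No sequence reads were analysed here.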

Results

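RNA levels were measured by sequencing in 9 libraries of cultured mouse cells, 3 cultures of each of 3 cell types. The NSC group holds wild-type neural stem cells from the subventricular zone, the germinal layer beside the lateral ventricles (cultures 1, 3 and 5). The LTR and NF1 groups (cultures 1 to 3 of each) hold tumour cells that were made from such stem cells. LTR carries the label lgT/Ras, and NF1 the label of Nf1 loss with shp53 and CDK4. The series names its lines GSC1 and GSC2, and which of the labels belongs to which is not given in the sources used here. Total counts were 36042825, 57231024 and 35543564 for NSC 1, 3 and 5, 31923803, 28600479 and 32736056 for LTR 1 to 3, and 34230788, 31383416 and 31181787 for NF1 1 to 3. Genes with at least 10 counts numbered 15742 to 15794 in NSC, 13857 to 14216 in LTR and 13719 to 15026 in NF1. A floor of 3 counts lay between 0.0541 CPM (counts scaled to library size) in NSC 3 and 0.114 CPM in LTR 2. Levels are given as mean CPM ± SD over the 3 cultures of a group, and log2 fold changes ± SE. Intervals and floors cover counting error only. Except for Anln in NF1, each named gene past the threshold lay on one side of NSC in all 3 libraries of the line.

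The first principal component of the log CPM held 70.6% of the variance and the next 8.9%. NSC libraries lay between -150.4 and -136.3 on the first component, LTR between 84.6 and 92.2, and NF1 1 and NF1 3 at 85.1 and 108.7. NF1 2 stood apart, at -21.2 on the first and -102.7 on the next component. Correlations of log CPM across genes were 0.953 to 0.991 within NSC and 0.963 to 0.985 within LTR. NF1 1 and NF1 3 correlated at 0.981, and NF1 2 with them at 0.936 and 0.911. NF1 2 correlated with the NSC libraries at 0.886 to 0.892, against 0.806 to 0.84 for NF1 1 and NF1 3. NSC 3 also differed from NSC 1 and NSC 5, with 116 genes of at least 10 CPM above 2 times the highest of the other 8 libraries.

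**Figure D1:**
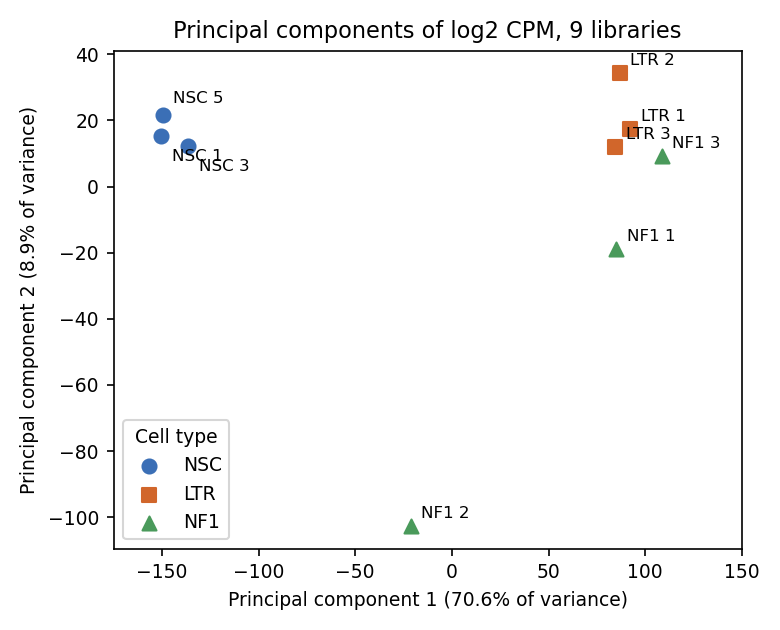
Position of each of the 9 libraries (points, coloured by group) on the principal components of log CPM that held 70.6% (horizontal) and 8.9% (vertical) of the variance. NSC libraries lie at -150.4 to -136.3 on the horizontal axis, and NF1 2 at -21.2, between NSC and the other 5 tumour libraries.

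The genes that the labels name were compared first. Trp53 (ENSMUSG00000059552, GRCm38 chromosome 11, 69580359 to 69591873), which encodes the p53 tumour suppressor, measured 107.6 ± 6.2 CPM in NSC. In the libraries labelled NF1, whose label names shp53, its mRNA was higher: 217, 151 and 221 CPM in NF1 1, 2 and 3 (log2 fold change 0.87 ± 0.2, adjusted p = 0.0141). The transcript was thus not below its level in wild-type cells, so the group is called the libraries labelled NF1. Cells of this line without shp53 were not measured, so a knockdown relative to such cells cannot be judged. The Trp53 call was lost without NSC 1 (adjusted p = 0.0599), NSC 5 (0.0635), NF1 1 (0.0573) or NF1 3 (0.0577), with 0.00153 to 0.0947 over all alternatives. Trp53 was also higher in LTR, at 252.9 ± 29.3 CPM (1.23 ± 0.2, adjusted p = 0.00258). Cdk4 (ENSMUSG00000006728, chromosome 10, 127063534 to 127067920), the kinase that partners D cyclins, measured 795, 393 and 1124 CPM in NF1 1, 2 and 3 against 371.5 ± 73 in NSC, where the highest library had 456. NF1 2 thus lay within the NSC range, and the group difference did not pass (1.05 ± 0.34, adjusted p = 0.053). Without NF1 2 it was 1.38 (adjusted p = 0.00175, range over alternatives 0.000753 to 0.216). In LTR, Cdk4 rose to 990.1 ± 47.7 CPM (1.41 ± 0.35, adjusted p = 0.0135). That call was lost without NSC 1 (adjusted p = 0.0549) or NSC 5 (0.0542), with 0.000396 to 0.0549 over all alternatives. Cdk4 overlaps Tspan31 on the other strand. Nf1 (ENSMUSG00000020716, chromosome 11, 79339693 to 79581612), which encodes the Ras GTPase activator neurofibromin, measured 102 ± 17.1 CPM in NSC and 59, 97.2 and 40.1 CPM in NF1 1, 2 and 3 (-0.64 ± 0.35, adjusted p = 0.205). Without NF1 2 the difference was -1.03 (adjusted p = 0.0248, range 0.0207 to 0.422). In LTR it was -0.78 ± 0.35 (adjusted p = 0.107), and -0.77 without NF1 2 (adjusted p = 0.0412, range 0.0368 to 0.341). Which exons were removed is not given in the sources used here, and the counts per gene include any exons that remained. Hras rose from 81.33 ± 11.6 CPM to 146.5 ± 22.7 in the libraries labelled NF1 (0.85 ± 0.25, adjusted p = 0.0367). This was lost without NSC 1 (adjusted p = 0.133), NSC 5 (0.119), NF1 1 (0.0562) or NF1 3 (0.0888), with 0.0079 to 0.135 over all alternatives. Hras in LTR measured 120.5 ± 38.9 CPM (adjusted p = 0.0991). Nras differed from NSC by -0.09 in LTR (adjusted p = 0.674) and by -0.08 in the libraries labelled NF1 (adjusted p = 0.736) on the log2 scale. No Ras construct has a count column of its own, so the Ras of the LTR label could not be read apart from the mouse genes.

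**Figure D2:**
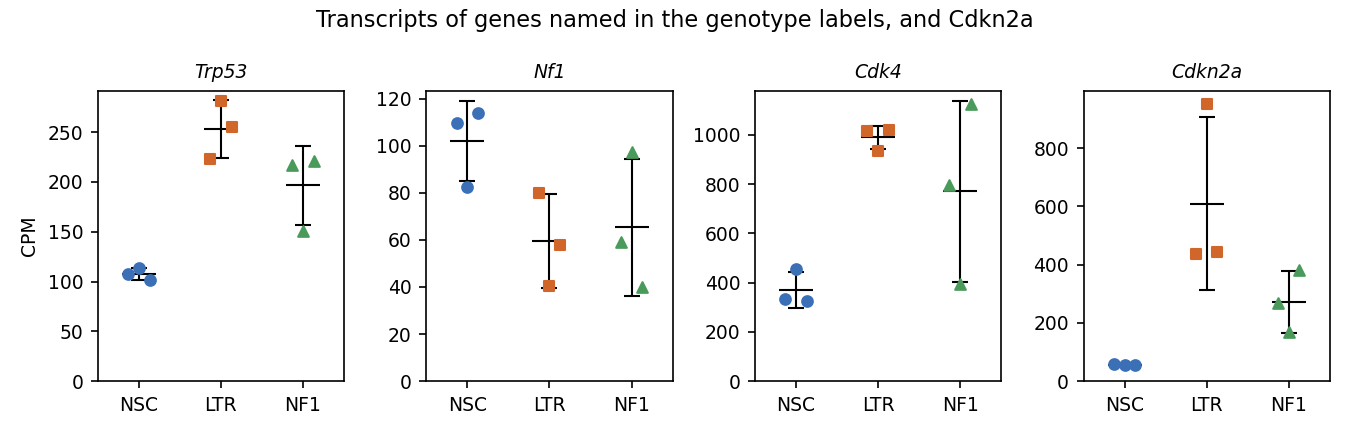
CPM of Trp53, Nf1, Cdk4 and Cdkn2a in each library (points), with the mean and SD of each group (bars). Trp53 lies at 151 to 221 CPM in the libraries labelled NF1 against 101 to 114 in NSC, and Cdk4 of NF1 2, at 393 CPM, lies within the NSC range.

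The LTR cells were compared with NSC to ask which transcripts differ between these tumour cells and wild-type stem cells. Of 21 neural stem cell markers 12 were lower and 2 higher in LTR, and of 16 astrocyte markers 15 were lower. These lists were called with a preset correlation, but not with an estimated one (adjusted p = 0.533 each). Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158), the receptor for EGF, fell from 190.8 ± 18.3 to 8.99 ± 1.98 CPM (-4.41 ± 0.41, adjusted p = 0.000458). Areg, a ligand of that receptor, rose from 0.315 ± 0.0777 to 47.03 ± 22.1 CPM (7.22 ± 0.47, adjusted p = 0.000114). Of 15696 genes tested, 5634 (35.9%) passed the edgeR quasi-likelihood test, 2346 higher and 3288 lower in LTR. Of these, 4470 differed at least 2-fold, 1628 higher and 2842 lower. The libraries of the groups did not overlap for 9256 genes (59%), where chance gives 10%. The count was 3281 without NSC 1, 3452 without NSC 5 and 3651 without LTR 3. Taking a GC content trend out of each library without centring it put 63.6% of the calls higher, against 41.6%, since the trends' own medians ran from -0.29 to 0.32 on the log2 scale. The file headers give all NSC libraries one lane number and all tumour libraries another, so lane and group cannot be told apart.

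Eph receptors and their ephrin ligands, which signal between neighbouring cells, changed in both directions in LTR. Of 19 members tested, 2 were higher, 5 lower and 12 did not pass (4 higher and 7 lower adjusted over the list alone), and the list as a whole was not called by camera (adjusted p = 0.478). Epha4 (ENSMUSG00000026235, chromosome 1, 77367185 to 77515088) fell from 68.08 ± 32.1 to 0.0679 ± 0.043 CPM (-9.96 ± 1.62, adjusted p = 0.00276), and Ephb2 (ENSMUSG00000028664, chromosome 4, 136647539 to 136835988) from 127.4 ± 42.4 to 7.86 ± 1.66 CPM (-4.02 ± 0.51, adjusted p = 0.00128). Efnb1 (ENSMUSG00000031217, chromosome X, 99136130 to 99148991) fell 5.59-fold, from 58.77 ± 5.28 to 10.51 ± 2.32 CPM (adjusted p = 0.00763). Ephb1 (ENSMUSG00000032537, chromosome 9, 101922128 to 102354693) fell by 5.53 on the log2 scale (adjusted p = 0.0121), -7.65 without LTR 2 and -4.79 without LTR 3. Efna1 (ENSMUSG00000027954, chromosome 3, 89271733 to 89281142), an ephrin that binds EphA2, rose from 0.982 ± 0.243 to 7.45 ± 0.136 CPM (2.92 ± 0.57, adjusted p = 0.00574). Epha2 (ENSMUSG00000006445, chromosome 4, 141301240 to 141329384) rose 2.21-fold, to 120.6 ± 17.5 CPM (adjusted p = 0.0144). It was not called without NSC 1 (adjusted p = 0.0592) or NSC 5 (0.0586), with 0.000487 to 0.0799 over all alternatives. Efna5 (ENSMUSG00000048915, chromosome 17, 62604184 to 62881317) fell 7.25-fold (adjusted p = 0.0446), a call lost on leaving out NSC 1, NSC 5 or any LTR library (adjusted p from 0.0917 to 0.135, and 0.000345 to 0.135 over all alternatives). Efnb2 (ENSMUSG00000001300, chromosome 8, 8617434 to 8661242) measured 196.6 ± 3.57 CPM in NSC and 159.8 ± 43.7 in LTR (-0.3 ± 0.27, adjusted p = 0.408). Without NF1 2 the higher members numbered 4, and without NSC 1 or NSC 5 there was 1.

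**Figure D3:**
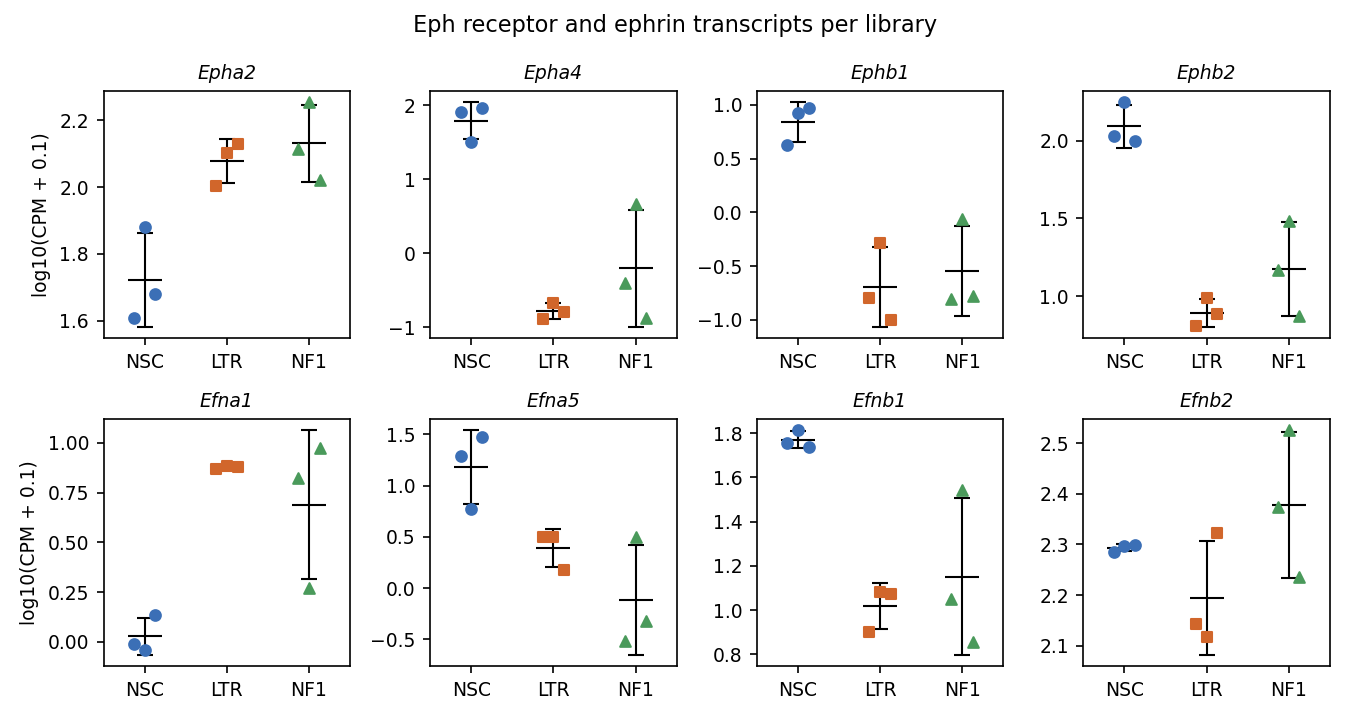
Log10(CPM + 0.1) of 8 Eph receptor and ephrin genes in each library (points), with the mean and SD of each group (bars). Epha4 and Ephb2 lie below NSC in every LTR library, Epha2 and Efna1 above, and Efnb2 measured 196.6 CPM in NSC, 159.8 in LTR and 247.9 in the libraries labelled NF1 on average.

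Among 42 other guidance cues and receptors, 3 were higher, 23 lower and 16 did not pass in LTR (5 and 24 adjusted over the list alone), and camera called the list lower (adjusted p = 0.000873, and adjusted p = 0.576 with an estimated correlation). Sema5b, a transmembrane semaphorin, fell from 130.9 ± 46.8 to 0.143 ± 0.0508 CPM (-9.83 ± 0.78, adjusted p = 0.000238). Ntn1, which encodes the axon guidance cue netrin-1, fell 62.6-fold from 390.4 ± 43.6 CPM (adjusted p = 0.00128). Sema7a rose 7.23-fold to 39.17 ± 16.5 CPM (adjusted p = 0.000972). The lower members numbered 15 without NSC 5, 13 without LTR 2 and 11 without LTR 3, and the higher ones 5 without NSC 3.

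All lineage lists of the neural tube were lower in LTR. Of 21 neural stem cell markers, 2 were higher, 12 lower and 7 did not pass (2 and 13 adjusted over the list alone, camera adjusted p = 8.01e-06, and adjusted p = 0.533 with an estimated correlation). Msi1, an RNA-binding protein of stem cells, fell 6.38-fold (adjusted p = 0.00112). Slc1a3 (ENSMUSG00000005360), a glutamate transporter of radial glia and astrocytes, fell from 771.3 ± 134 to 0.068 ± 0.0602 CPM (-13.46 ± 1.53, adjusted p = 0.000919), -12.84 without LTR 1. Pax6 and Fut4 were the higher members, and without single libraries their count was 0 (NSC 1, NSC 5) or 1 (NSC 3, NF1 1 and each LTR library). Nestin (Nes) measured 1481 ± 97 CPM in NSC and 625.7 ± 201 in LTR (adjusted p = 0.111), and vimentin (Vim) 6995 ± 746 and 8489 ± 2710 (adjusted p = 0.463). Of 16 astrocyte markers, 15 were lower and 1 did not pass (15 adjusted over the list alone, camera adjusted p = 8.3e-08, and adjusted p = 0.533 with an estimated correlation). Aldoc, a brain aldolase, fell from 242 ± 9.92 to 21.7 ± 3.1 CPM (-3.48 ± 0.37, adjusted p = 0.000777), while the gap junction gene Gja1 measured 263.8 ± 63.6 and 244.8 ± 63.6 CPM (adjusted p = 0.801). Of 15 oligodendrocyte lineage markers, 9 were lower and 6 did not pass (9 adjusted over the list alone, camera adjusted p = 9.72e-06, and adjusted p = 0.533 with an estimated correlation). Sox8 fell 14.8-fold and the progenitor antigen gene Cspg4 16.1-fold (adjusted p = 0.000718 for each), and Olig2, a transcription factor of that lineage, from 814.3 ± 101 to 62.16 ± 24.5 CPM (adjusted p = 0.00285).

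Of 15 neuronal markers, 1 was higher, 8 lower and 6 did not pass in LTR (1 and 9 adjusted over the list alone, camera adjusted p = 0.00955, and adjusted p = 0.533 with an estimated correlation). A filter of 10 CPM in 3 libraries gave the list an adjusted p of 0.276 (range over alternatives 0.00177 to 0.533). Gad1, an enzyme of GABA synthesis, fell 16.4-fold from 3.82 ± 1 CPM (adjusted p = 0.00371). The single higher member was not called without NSC 1, NSC 5, LTR 2, LTR 3 or NF1 1. All 4 ependymal markers tested were lower (4 adjusted over the list alone, camera adjusted p = 0.00806, and adjusted p = 0.533 with an estimated correlation), among them Foxj1, the regulator of motile cilia, at 165.1 ± 57.1 against 0.485 ± 0.0442 CPM (adjusted p = 0.00162). Their count was 2 without NSC 1 and 7, with more members tested, without NSC 3 or any NF1 library. Markers of cells that a brain culture can carry over were also read. Of 4 microglia and myeloid markers tested (11 had too few counts), 2 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.553), with median 1.45 and mean -0.31. Laptm5, a leukocyte membrane protein gene, was the more abundant of the risen ones at 2.95 ± 1.82 CPM (2.56 on the log2 scale, 3.31 without NSC 3), not called without NSC 1 (adjusted p = 0.0574) or NSC 5 (0.0581), with 0.000274 to 0.105 over all alternatives. Those higher numbered 0 without NSC 1 and 1 without NSC 5 or LTR 2. Of 9 endothelial markers, 2 were higher and 2 lower (3 and 2 adjusted over the list alone, adjusted p = 0.927), with median -0.89 and mean -1.24 though camera's direction was up. The VEGF receptor gene Flt1 rose 7.14-fold to 31.65 ± 3.89 CPM (adjusted p = 0.0114), and 1 member was higher without NSC 1. Of 7 mural cell and fibroblast markers, 2 were higher and 5 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.0493, and adjusted p = 0.576 with an estimated correlation). Col1a1, a chain of type I collagen, fell from 374.9 ± 318 to 2.98 ± 1 CPM (-6.98 ± 1.16, adjusted p = 0.00294), and its NSC level differed between cultures, with 487.1, 16.51 and 621.2 CPM in NSC 1, 3 and 5. The list was not called without NSC 1 (adjusted p = 0.0604), LTR 1 (0.0738), NF1 1 (0.0504), NF1 2 (0.103) or NF1 3 (0.0607), or on ranks (0.146), with 3.99e-06 to 0.576 over all alternatives, and 1 member was higher without NSC 5.

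Of 32 G1/S genes, 6 were higher in LTR (3 adjusted over the list alone, camera adjusted p = 0.000873, and adjusted p = 0.713 with an estimated correlation), and of 25 G2/M genes, 6 (0 adjusted over the list alone, camera adjusted p = 0.00274, and adjusted p = 0.713 with an estimated correlation). The fry test, which asks whether members move one way on balance, gave 0.17 and 0.179. E2f1, a transcription factor of S phase entry, rose from 41.89 ± 0.26 to 91.23 ± 10.3 CPM (1.12 ± 0.22, adjusted p = 0.00551). Without NF1 2, which shares the estimate of the spread, 22 G1/S and 16 G2/M genes were higher. The G1/S count was 1 without NSC 1 and 3 without NSC 3, NSC 5 or LTR 3, and the G2/M count 0 without NSC 1 or NSC 5, 2 without LTR 1 and 1 without LTR 2 or LTR 3. Of 25 cytokinesis genes, 2 were higher and 23 did not pass (0 adjusted over the list alone, camera adjusted p = 0.301). Anln, the scaffold of the contractile ring, rose from 134 ± 28.1 to 368.9 ± 32.7 CPM (1.46 ± 0.35, adjusted p = 0.0123), and was not called without NSC 1 (adjusted p = 0.0506, range 0.000351 to 0.0506). The count was 0 without NSC 1, 1 without NSC 3, LTR 2 or LTR 3, and 7 higher with 3 lower without NF1 2, and 1 was lower without NSC 3 or NF1 1.

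Of 28 p53 targets, 17 were lower, none higher and 11 did not pass in LTR (19 lower adjusted over the list alone, camera adjusted p = 2.97e-05, and adjusted p = 0.543 with an estimated correlation). The death receptor gene Fas fell from 21.51 ± 7.84 to 0.479 ± 0.111 CPM (-5.48 ± 0.57, adjusted p = 0.000718) and Zmat3 fell 5.56-fold (adjusted p = 0.00238), while Mdm2, the ubiquitin ligase for p53, measured 123.6 ± 9.69 and 167.5 ± 49.3 CPM (adjusted p = 0.17). The lower members numbered 11 without LTR 2, where 2 were higher, and 9 without LTR 3. Of 13 cyclin D, INK4 and RB genes, 3 were higher and 5 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.678, and 0.00528 by fry). The inhibitor genes Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) and Cdkn2b rose from 56.26 ± 3.26 to 609.4 ± 296 CPM (3.44 ± 0.4, adjusted p = 0.000984) and from 45.08 ± 1.59 to 176.3 ± 46.2 CPM (adjusted p = 0.00129). Cdk6 fell 8.42-fold (adjusted p = 0.00147) and Ccnd3 2.43-fold (adjusted p = 0.00132). The lower members numbered 3 without NSC 3 or any LTR library. Of 23 MAPK output genes, 6 were higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.0848), with median -0.1 and mean 0.49. Besides Areg, the phosphatase gene Dusp5 rose 5.42-fold (adjusted p = 0.0013), Fosl1, an AP-1 subunit, 4.42-fold (adjusted p = 0.00182) and Myc 2.8-fold (adjusted p = 0.00218). The list was called higher without NSC 3 (adjusted p = 0.00383) or LTR 1 (0.0107) and without a low-count filter (0.0257), with 0.00383 to 0.713 over all alternatives, and 1 member was lower without NSC 3, LTR 2 or LTR 3.

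Of 34 integrins and basement membrane genes, 4 were higher, 17 lower and 13 did not pass in LTR (4 and 18 adjusted over the list alone, camera adjusted p = 0.000526, and adjusted p = 0.576 with an estimated correlation). The laminin chain gene Lamc1 fell from 454.2 ± 58.6 to 135.6 ± 34.7 CPM (-1.74 ± 0.24, adjusted p = 0.00147) and Itgb5 fell 3.2-fold (adjusted p = 0.000718). Without NSC 1, 2 were higher. Of 21 matrix proteases and inhibitors, 1 was higher, 14 lower and 6 did not pass (1 and 14 adjusted over the list alone, camera adjusted p = 8.83e-06, and adjusted p = 0.533 with an estimated correlation). Mmp14, a membrane-bound collagenase, fell from 404.3 ± 23.7 to 39.28 ± 3.69 CPM (-3.36 ± 0.3, adjusted p = 0.00042) and Adam12 fell 12.4-fold (adjusted p = 0.000305). The lower ones numbered 9 without NSC 1 or LTR 1, 8 without NSC 5 and 7 without LTR 2 or LTR 3, and the higher one was not called on leaving out any single NSC or LTR library. Of 16 Notch pathway genes, 2 were higher, 12 lower and 2 did not pass (2 and 13 adjusted over the list alone, camera adjusted p = 0.00105, and adjusted p = 0.533 with an estimated correlation). Lfng, a glycosyltransferase acting on Notch, fell from 225.9 ± 40.5 to 20.02 ± 3.02 CPM (-3.5 ± 0.21, adjusted p = 8.26e-05), while the receptor gene Notch4 rose 9.21-fold to 24.08 ± 3.97 CPM (adjusted p = 0.00128). Without LTR 1, LTR 2 or LTR 3, 7 were lower. Of 26 mesenchymal glioma genes, 8 were higher and 7 lower (10 and 7 adjusted over the list alone, camera adjusted p = 0.101). Plau, the urokinase gene, rose 21.8-fold and Timp1, a metalloproteinase inhibitor, 10.8-fold (adjusted p = 0.000853 and 0.00128). This list was called higher without LTR 1 (adjusted p = 0.0241) or LTR 3 (0.0412, with 3 lower) and without a low-count filter (0.0385), and its adjusted p ranged from 0.0241 to 0.576 over all alternatives. Of 7 EMT genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.836, 0.0423 under the filter of 10 CPM and 0.0423 to 0.937 over all alternatives), with median -0.18 and mean 0.82. The repressor gene Zeb1 fell 3.63-fold and Cdh2, the N-cadherin gene, 3.43-fold (adjusted p = 0.00171 and 0.00228). Twist2 was the higher member, at 9.03 on the log2 scale, and at 11.83 without NSC 3. The higher members numbered 3 without NSC 3 and 2 without NSC 1, LTR 1, LTR 3, NF1 1 or NF1 3.

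Of 10 Hox genes tested, 8 were higher in LTR and 2 did not pass (9 adjusted over the list alone, camera adjusted p = 9.33e-08, and adjusted p = 0.533 with an estimated correlation), and 13 were higher without NF1 2, when more could be tested. The other 29 of 39 Hox genes were too low to test. Those tested measured 0 to 0.1323 CPM in NSC and passed the low-count filter through the tumour libraries, so they could be called only higher in either tumour group, and their count and list direction were largely set by the filter. Hox genes set position along the body axis and are silent in the forebrain. Hoxa3 had no count in any NSC library and 6.99 ± 1.14 CPM in LTR, at least 309-fold higher over the floor of 3 counts for the group (adjusted p = 0.000936), and it overlaps antisense transcripts. Of 20 imprinted genes, 1 was higher, 8 lower and 11 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 0.00806, and adjusted p = 0.543 with an estimated correlation). Mest fell from 1218 ± 167 to 85.48 ± 20.2 CPM (-3.83 ± 0.35, adjusted p = 0.00042) and Peg10 6.06-fold (adjusted p = 0.00132). The lower ones numbered 5 without NSC 1 or any LTR library, and the higher one was not called without NSC 1 or NSC 5. Of 22 glycolysis and hypoxia genes, 9 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00298, and adjusted p = 0.533 with an estimated correlation). Pfkl, a phosphofructokinase, rose from 75.78 ± 7.01 to 242.4 ± 26.4 CPM (1.68 ± 0.22, adjusted p = 0.00131). Of 22 cholesterol synthesis genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.102). Msmo1, a sterol oxidase, rose 2.24-fold (adjusted p = 0.0181), and neither it nor any other member was called without NSC 1 (adjusted p of Msmo1 0.0705) or NSC 5 (0.069), with 0.00506 to 0.0915 over all alternatives. There were 4 higher without LTR 1 or LTR 2, none lower without NSC 3 or any LTR library, and the list was called higher without NSC 3 (adjusted p = 0.0116), LTR 1 (0.0445) or LTR 3 (0.0482) and without a low-count filter (0.0406), with 0.0116 to 0.736 over all alternatives.

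Of 18 interferon-stimulated genes, 1 was higher and 8 lower in LTR (1 and 8 adjusted over the list alone, camera adjusted p = 0.295). Ddx58, the RNA sensor RIG-I, fell 5.19-fold (adjusted p = 0.00734). The lower ones numbered 5 without NSC 1, NSC 5 or LTR 2 and 4 without LTR 3. Of 11 MHC class I presentation genes, 3 were higher and 4 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.999). The chains H2-D1 and B2m rose 3.27-fold and 3-fold (adjusted p = 0.00235 and 0.00256), while the peptide transporter gene Tap1 fell 6.51-fold (adjusted p = 0.0024). Of 14 immediate early and heat shock genes, 2 were higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.337), with median 0.31 and mean -0.35. Fos fell by 6.81 on the log2 scale (adjusted p = 0.00286), and by 4.58 without NSC 3. In NSC 1, 3 and 5 it measured 36.13, 337.3 and 25.96 CPM, and Hspa8 457.5, 1803 and 483.4 CPM. Without NSC 3, 7 members were higher and the list was called (adjusted p = 0.034, range 0.034 to 0.836). Without NSC 1 or NSC 5 none was higher and 2 were lower, and without NF1 1 or any LTR library 1 was higher. None of the 10 mitochondrially encoded mRNAs tested passed by edgeR, also adjusted over the list alone (median -0.11, camera adjusted p = 0.999), with mt-Co1 at 4650 ± 596 CPM in NSC and 3869 ± 1820 in LTR.

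The steepest increases in LTR, among genes of at least 8 CPM, were of genes with no count in any NSC library. They included Gpr149 (27.58 ± 36.8 CPM, at least 1260-fold higher, adjusted p = 0.00563), the intestinal regulator Cdx2 (14.89 ± 11 CPM, at least 648-fold, adjusted p = 0.00539), the homeobox gene Lhx1 (13.74 ± 8.87 CPM, at least 614-fold, adjusted p = 0.00192) and the placental homeobox gene Esx1 (8.49 ± 6.72 CPM, at least 344-fold, adjusted p = 0.00132). Their levels differed between cultures: in LTR 1, 2 and 3 Gpr149 measured 69.88, 9.956 and 2.896 CPM, Cdx2 25.85, 14.99 and 3.821, Lhx1 23.96, 9.27 and 8.001 and Esx1 2.431, 15.72 and 7.314, so the bounds depend on single libraries. Kcnq1 and Shox2, also at 0 in NSC, overlap Kcnq1ot1 and Rsrc1 on the other strand. Genes with no count in any LTR library led the decreases. Among them were the AMPA receptor gene Gria2 (71.36 ± 43.3 CPM in NSC, at least 2010-fold lower, adjusted p = 0.00226), the surface antigen gene Thy1 (63.58 ± 12.5 CPM, at least 2020-fold, adjusted p = 0.000777) and Lrrn2 (62.65 ± 5 CPM, at least 1940-fold, adjusted p = 0.00166).

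The libraries labelled NF1 were compared with NSC by the same test and lists. Egfr was lower, at 3.13 ± 1.9 CPM (-5.93 ± 0.44, adjusted p = 0.000203), and at -6.53 without NF1 2. Adam12, a surface metalloprotease, fell from 257.3 ± 8.93 to 9.67 ± 1.99 CPM (-4.73 ± 0.32, adjusted p = 0.000163), and Areg rose 132-fold to 41.53 ± 10.7 CPM (7.04 ± 0.47, adjusted p = 0.000163). Of the 15696 genes, 3631 (23.1%) passed, 1578 higher and 2053 lower in the libraries labelled NF1, and 2937 of them differed at least 2-fold (1113 higher, 1824 lower). The groups' libraries did not overlap for 6647 genes (42.3%, chance 10%). Without NF1 2, 6900 genes passed, 3555 of the 3631 among them, against 1752 without NSC 1, 1857 without NSC 5, 1898 without NF1 1 and 2373 without NF1 3. With the GC trends not centred, 64.3% of calls were higher, against 43.5%.

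Of the 19 Eph receptors and ephrins, 4 were higher, 6 lower and 9 did not pass in the libraries labelled NF1 (4 and 6 adjusted over the list alone, camera adjusted p = 0.547). Ephb2 fell from 127.4 ± 42.4 to 17.42 ± 11.7 CPM (-2.87 ± 0.48, adjusted p = 0.00447), and Epha4 to 1.62 ± 2.53 CPM (-5.39 ± 1.23, adjusted p = 0.0145). Without NF1 2 they were at -3.52 and -8.61. Epha2 rose from 54.65 ± 18.6 to 138.3 ± 37.8 CPM (1.34 ± 0.29, adjusted p = 0.0113), and was not called without NSC 5 (adjusted p = 0.051, range 0.000903 to 0.0701). Efna1 rose 6.01-fold to 5.91 ± 3.86 CPM (adjusted p = 0.0124), and was not called without NSC 1 (adjusted p = 0.0545, range 3.53e-05 to 0.0545). Efna3 and Efna4 rose 2.51-fold and 1.84-fold, and Ephb1, Epha3, Efna5 and Efnb1 fell (adjusted p from 0.0226 to 0.038). Each of these 6 calls was lost without NSC 1 or NSC 5, those of the 4 lower genes also without NF1 1 or NF1 3. Efna3 was not called either without NF1 1, Efna4 without NF1 3, Epha3 and Efnb1 without NSC 3, and Efnb1 without LTR 3, with adjusted p from 0.0517 to 0.122 in these cases. Without NF1 2, Ephb1, Efna5 and Efnb1 moved from -4.57, -3.91 and -1.73 to -6.75, -5.96 and -2.67. Epha3 (-5.13) had no count in NF1 1 or NF1 3 and was at -4.54 without NF1 1. Epha5 and Epha7 did not pass (-2.46 and 0.25). Without NF1 2, Epha5 had no count left in the libraries labelled NF1 (adjusted p = 0.00012, range 0.00012 to 0.392), and Epha7 was at -2.25 (adjusted p = 0.0341, range 0.0341 to 0.984). Efnb2 measured 247.9 ± 81.9 CPM (0.33 ± 0.27, adjusted p = 0.389). By count, 1 was higher and 2 lower without NSC 1 or NSC 5, and 2 lower without NF1 1 or NF1 3. Of 42 other guidance cues, 4 were higher, 20 lower and 18 did not pass (4 and 20 adjusted over the list alone, camera adjusted p = 0.000638, and adjusted p = 0.44 with an estimated correlation). Nrp1, a semaphorin co-receptor, fell 2.77-fold (adjusted p = 0.00461), and Nrp2 rose from 8.18 ± 3.64 to 196.5 ± 190 CPM (4.59 ± 0.74, adjusted p = 0.00382), 3.46 without NF1 2. There was 1 higher without NSC 1, NSC 5 or NF1 1, and the lower ones numbered 11, 12 and 10.

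The lineage lists were called lower with a preset correlation, as in LTR, though fewer members passed as lower in all but the neuronal list. Their medians lay further below NSC without NF1 2. Of 21 neural stem cell markers, 7 were lower and 14 did not pass (9 adjusted over the list alone, camera adjusted p = 7.04e-06, and adjusted p = 0.397 with an estimated correlation), and Msi1 fell 5.65-fold (adjusted p = 0.00176). Without NF1 2, 13 were lower and 1 higher. Vim and Nes measured 10370 ± 334 and 1178 ± 1090 CPM (adjusted p = 0.173 and 0.694). Of 16 astrocyte markers, 11 were lower and 5 did not pass (13 adjusted over the list alone, camera adjusted p = 1.86e-07, and adjusted p = 0.397 with an estimated correlation), with Aldoc at 26.22 ± 15.2 CPM (-3.21 ± 0.37, adjusted p = 0.00122). There were 7 lower without NSC 1, NSC 5 or NF1 1. Of 15 oligodendrocyte lineage markers, 8 were lower and 7 did not pass (8 adjusted over the list alone, camera adjusted p = 0.000132, and adjusted p = 0.397 with an estimated correlation). Sox8 fell 6.83-fold and Cspg4 4.97-fold (adjusted p = 0.00221 and 0.00419), and 4 were lower without NSC 1 or NF1 1 and 5 without NSC 5 or NF1 3. Of 15 neuronal markers, 1 was higher, 8 lower and 6 did not pass (1 and 8 adjusted over the list alone, camera adjusted p = 0.0274, and adjusted p = 0.397 with an estimated correlation), and the filter of 10 CPM gave 0.613 (range 0.00367 to 0.613). Elavl4, a neuronal RNA-binding protein, fell 5.05-fold (adjusted p = 0.011). The lower ones numbered 4 without NSC 1, 3 without NSC 5, 2 without NF1 1 and 4 without NF1 3, and the higher ones 2 without NSC 3 and 0 without NSC 1, NSC 5 or NF1 1. Of 4 ependymal markers, 2 were lower (3 adjusted over the list alone, camera adjusted p = 0.0162, and adjusted p = 0.397 with an estimated correlation). Foxj1 fell to 2.12 ± 3.04 CPM (-6.28 ± 1.04, adjusted p = 0.00424), -8.77 without NF1 2. Their count was 1 without NF1 1, 7 without NF1 2, 4 without NF1 3 or LTR 1 and 5 without NSC 3, LTR 2 or LTR 3, when more could be tested.

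Of 4 microglia and myeloid markers, 2 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.371), all of them calls that single libraries ended: the lower one without any library except NF1 2, and the higher ones numbered 0 without NSC 1 or NSC 5 and 1 without NSC 3, NF1 1 or NF1 3. Of 9 endothelial markers, 2 were higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.639), with median 0.17 and mean -0.26. Flt1 rose to 73.76 ± 71.4 CPM (4.06 ± 0.7, adjusted p = 0.00492), 2.9 without NF1 2. Without any single library except NF1 2, 1 member was lower, and 1 was higher without NSC 1. Of 7 mural cell and fibroblast markers, 5 were lower (5 adjusted over the list alone, camera adjusted p = 0.00106, and adjusted p = 0.397 with an estimated correlation). Col1a1 fell 274-fold to 1.36 ± 0.517 CPM (-8.1 ± 1.22, adjusted p = 0.0029) from the NSC levels given above, which NSC 1 and NSC 5 set. The list was not called without NF1 2 (adjusted p = 0.0612, range 2.22e-08 to 0.397), and 1 member was higher without NF1 1 or NF1 3.

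Of the cell cycle lists none was called in the libraries labelled NF1, and each moved with NF1 2. Of 32 G1/S genes, 2 were higher (1 adjusted over the list alone, camera adjusted p = 0.0766), with E2f1 at 94.4 ± 25.3 CPM (1.17 ± 0.22, adjusted p = 0.00652). Without NF1 2, 23 were higher and the list was called (adjusted p = 1.08e-06), as it was without NSC 3 (0.0343), on ranks (0.0415) and without a low-count filter (0.0258), with 8.07e-07 to 0.814 over all alternatives. Without any other library except LTR 2, 1 was higher. Of 25 G2/M genes, none passed by edgeR, also adjusted over the list alone (camera adjusted p = 0.156), and without NF1 2, 17 were higher (adjusted p = 6.27e-06, range 6.27e-06 to 0.875). Cdk1, the mitotic kinase, measured 161.4 ± 33.3 CPM in NSC and 390.5 ± 253 in the libraries labelled NF1 (adjusted p = 0.09). Of 25 cytokinesis genes, only Anln passed (0 adjusted over the list alone, camera adjusted p = 0.948), at 293.9 ± 134 CPM (adjusted p = 0.0433). It was lost without any 1 of NSC 1, 3 or 5, LTR 1, LTR 3, NF1 1 or NF1 3 (range over alternatives 0.000716 to 0.14). Without NF1 2, 6 cytokinesis genes were higher and 2 lower, 2 were lower without NSC 3 and 1 without NF1 1.

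Of 28 p53 targets, 9 were lower and 19 did not pass in the libraries labelled NF1 (9 adjusted over the list alone, camera adjusted p = 7.73e-05, and adjusted p = 0.405 with an estimated correlation). Zmat3 fell 3.83-fold (adjusted p = 0.008) and Fas fell to 0.625 ± 0.402 CPM (-5.1 ± 0.56, adjusted p = 0.00107), -5.75 without NF1 2. The lower ones numbered 20 without NF1 2, 5 without NSC 1 or NSC 5 and 3 without NF1 1, and 1 was higher without LTR 2. Of 13 cyclin D, INK4 and RB genes, 2 were higher and 3 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.639, and 0.0239 by fry). Cdkn2a rose to 272.3 ± 106 CPM and Cdkn2b to 124.8 ± 33.4 CPM (2.28 ± 0.38 and 1.47 ± 0.25, adjusted p = 0.00447 and 0.00451), while Cdk6 fell 9.17-fold (adjusted p = 0.00184). Without NF1 2, 4 were higher. Of 23 MAPK output genes, 6 were higher and 2 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.44 with an estimated correlation). Fosl1 rose 5.61-fold and Dusp5 4.93-fold (adjusted p = 0.00172 and 0.00206). The list was not called without NF1 2 (adjusted p = 0.0612), on ranks (0.13) or by fry (0.0641), with 0.000342 to 0.44 over all alternatives. There was 1 lower without any NSC library or LTR 3, and none without NF1 1 or NF1 3.

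Of 34 integrins and basement membrane genes, 4 were higher and 15 lower (4 and 18 adjusted over the list alone, camera adjusted p = 0.000422, and adjusted p = 0.44 with an estimated correlation), with Lamc1 3.87-fold and Itgb5 2.8-fold lower (adjusted p = 0.00146 and 0.00132). There were 9 lower without NSC 1, NSC 5 or NF1 1, and 2 higher without NSC 1. Of 21 matrix proteases and inhibitors, 1 was higher and 10 lower (1 and 11 adjusted over the list alone, camera adjusted p = 4.62e-05, and adjusted p = 0.397 with an estimated correlation), with Mmp14 3.81-fold lower (adjusted p = 0.00274). There were 6 lower without NSC 1, NSC 5, NF1 1 or NF1 3, and none higher without NSC 1 or NSC 5. Of 16 Notch pathway genes, 1 was higher and 7 lower (2 and 9 adjusted over the list alone, camera adjusted p = 0.0024, and adjusted p = 0.397 with an estimated correlation). Lfng fell 7.05-fold and Notch4 rose 20.3-fold (adjusted p = 0.000163 and 0.000689). Without NF1 2, 12 were lower, and 2 were higher without NSC 3. Of 26 mesenchymal glioma genes, 9 were higher and 6 lower (11 and 7 adjusted over the list alone, camera adjusted p = 0.0225, and adjusted p = 0.397 with an estimated correlation). Plau rose 21.9-fold, Timp1 12.1-fold and the receptor gene Met 3.37-fold (adjusted p = 0.00116, 0.00146 and 0.00161). Spp1, the osteopontin gene, rose to 5475 ± 3380 CPM (4.38 ± 0.47, adjusted p = 0.00102), 3.75 without NF1 2. The list was not called without NSC 3 (adjusted p = 0.226), on ranks (0.134) or under the filter of 10 CPM (0.0527), with 0.0042 to 0.397 over all alternatives, and 3 were lower without NSC 1. Of 7 EMT genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.865, 0.039 under the filter of 10 CPM and 0.039 to 0.994 over all alternatives), with median -0.33 and mean 0.84, and Zeb1 fell 3.46-fold (adjusted p = 0.00269). Twist2 was the higher member here too, at 8.19 on the log2 scale, and at 10.98 without NSC 3. The higher ones numbered 3 without NSC 3 and 2 without LTR 1, LTR 3 or NF1 3.

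Of 10 Hox genes, 9 were higher in the libraries labelled NF1 (10 adjusted over the list alone, camera adjusted p = 1.86e-07, and adjusted p = 0.397 with an estimated correlation), and Hoxa4 measured 3.12 ± 2.18 CPM, at least 137-fold above NSC, where it had no count (adjusted p = 0.00327). Of 20 imprinted genes, 1 was higher and 7 lower (1 and 11 adjusted over the list alone, camera adjusted p = 0.000638, and adjusted p = 0.397 with an estimated correlation), with Mest 9.14-fold and Peg10 10.3-fold lower (adjusted p = 0.001 and 0.000986). There were 4 lower and none higher without NSC 1, NSC 5 or NF1 1, and 11 lower without NF1 2. Of 22 glycolysis and hypoxia genes, 8 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00366, and adjusted p = 0.397 with an estimated correlation). Bnip3 rose 3.3-fold and Pfkl 2.45-fold (adjusted p = 0.00276 and 0.0042). There were 5 higher without NSC 1 or NSC 5, and 1 lower without NF1 1 or any NSC or LTR library. Of 22 cholesterol synthesis genes, 1 was higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.795). Hmgcs1 fell 2.06-fold from 1029 ± 117 CPM (adjusted p = 0.0158), and was not called without NSC 1 (adjusted p = 0.0508), NSC 3 (0.0586) or NF1 1 (0.0682), with 0.00202 to 0.0682 over all alternatives. The higher ones numbered 0 without NSC 1, NSC 5, LTR 3 or NF1 3, 2 without NSC 3 or LTR 2, and 4 (with 2 lower) without NF1 2.

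Of 18 interferon-stimulated genes, 6 were lower in the libraries labelled NF1 (7 adjusted over the list alone, camera adjusted p = 0.0485, and adjusted p = 0.51 with an estimated correlation). Gbp3, a guanylate-binding protein, fell 6.46-fold (adjusted p = 0.0154), with -1.93 without NSC 3 and -3.36 without NF1 2 against -2.69, and was not called without NF1 1 (adjusted p = 0.0609, range 3.38e-05 to 0.0609). The list's call was lost without any 1 library except NSC 3 and NF1 1 (adjusted p = 0.0684, 0.131, 0.064, 0.0663, 0.0546, 0.22 and 0.0598 without NSC 1, NSC 5, LTR 1, LTR 2, LTR 3, NF1 2 and NF1 3), with DESeq2 size factors (0.0533), with library totals (0.0552) and under the filter of 10 CPM (0.347), over a range of 0.00975 to 0.51. The lower ones numbered 1 without NSC 1 or NF1 1, 2 without NSC 5 and 3 without NF1 3. Of 11 MHC class I presentation genes, 3 were higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.932), with median -0.63 and mean -0.33 though camera's direction was up. Nlrc5, the transactivator of these genes, rose 14-fold and B2m 3.69-fold (adjusted p = 0.00206 and 0.00209), and Tap1 fell 6.37-fold (adjusted p = 0.00353). Of 14 immediate early and heat shock genes, 2 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.177), with median 0.23 and mean -0.12. Fos fell by 5.8 on the log2 scale (adjusted p = 0.00607), with -3.64 without NSC 3 and -6.49 without NF1 2. Without NSC 3, 5 were higher and the list was called (adjusted p = 0.0118, range 0.0118 to 0.802), without NSC 1 none was, and without NSC 5 or NF1 1, 1 was. No mitochondrially encoded mRNA of 10 passed by edgeR, also adjusted over the list alone, while camera called the list higher (median 0.79, adjusted p = 0.0325, and adjusted p = 0.599 with an estimated correlation). It was not called without NSC 3 (adjusted p = 0.106), NF1 2 (0.157) or NF1 3 (0.0939), by fry (0.137) or under the filter of 10 CPM (0.152), with 0.000677 to 0.599 over all alternatives, and 1 was higher without NF1 1.

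The largest increases among genes of at least 8 CPM were of Grem1, a BMP antagonist, and Calcb, a neuropeptide of the calcitonin family. Grem1 measured 391.2 ± 627 CPM in the libraries labelled NF1, of which NF1 2 had 1115 (10.54 ± 1.92, adjusted p = 0.00605). It was at 6.81 without NF1 2 and 12.45 without NSC 3, and was not called by DESeq2 or limma-voom (6.24e-05 to 0.0587 over all alternatives). Calcb measured 16.16 ± 12.1 CPM, a ratio of 2180 to NSC (95% counting interval 391 to 86200, adjusted p = 0.00108), with a fitted log2 change of 10.48 and 9.69 without NF1 1, and no count in NSC 3 or NSC 5. Rnf183, a ubiquitin ligase, measured 12.59 ± 2.24 CPM, a ratio of 818 (226 to 6760, adjusted p = 0.000163). Smooth muscle actin (Acta2) fell from 626.4 ± 404 to 0.0534 ± 0.0924 CPM (-13.44 ± 1.55, adjusted p = 0.00127), and NF1 1 and NF1 3 had none. It was at -12.83 without NF1 1. Its NSC levels were 796.4, 165 and 917.9 CPM in NSC 1, 3 and 5. Grb10, an imprinted adaptor gene, fell to 0.0397 ± 0.044 CPM (-10.24 ± 1.67, adjusted p = 0.00387), -11.4 without NF1 1.

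**Figure D4:**
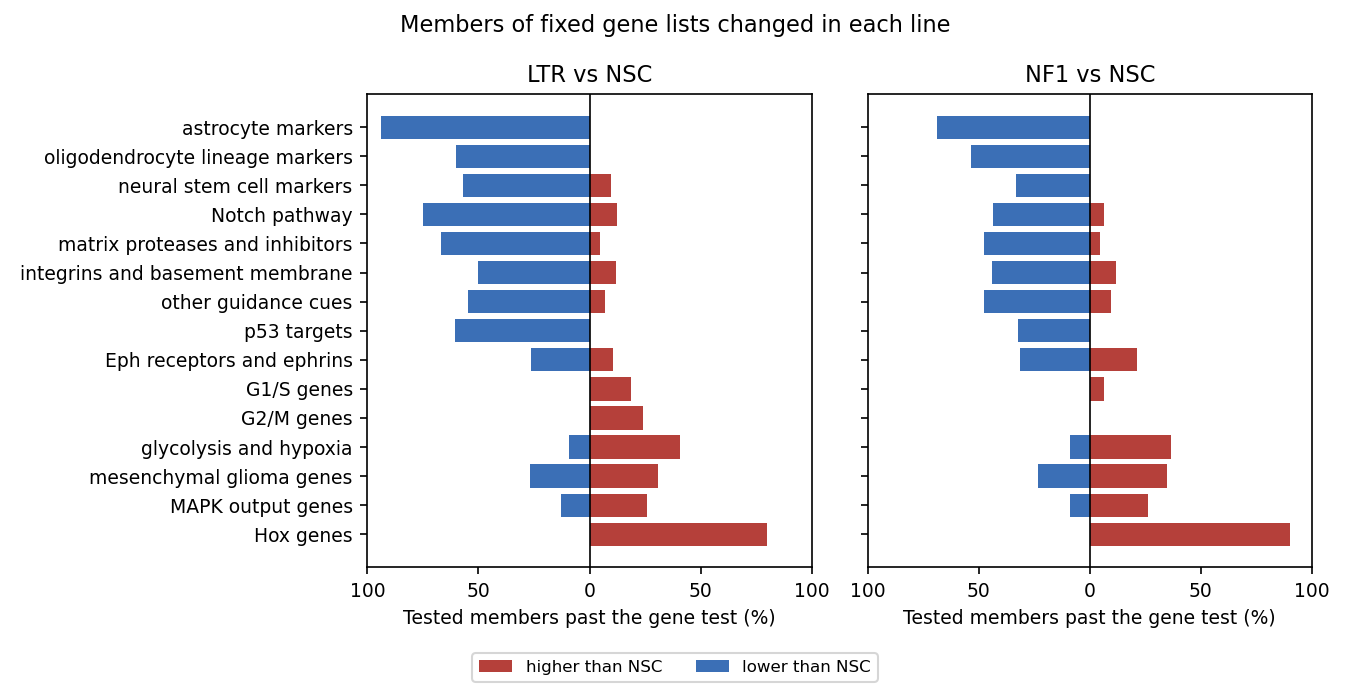
Percent of the tested members of 15 gene lists that passed the edgeR test as higher (right) or lower (left) than NSC, in LTR and in the libraries labelled NF1 (bars). Of 16 astrocyte markers 15 and 11 were lower, and of 10 Hox genes 8 and 9 were higher.

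Both tumour groups were set against the same NSC libraries, and many genes were called in both. In both, 1301 genes were higher and 1838 lower, against 235.9 and 430.1 for independent lists of these sizes. These made up 82.4% and 89.5% of the calls in the libraries labelled NF1. Fold changes correlated across genes at r = 0.888, and 87.1% had the same sign. In 20 simulations of unchanged groups, all 9 libraries, NSC included, were drawn gene by gene at the NSC means. There r averaged 0.499 (0.477 to 0.511), 66.5% of signs were shared and no gene was called in both. As no gene was changed in these simulations, almost no call was possible. Their lack of joint calls therefore sets no scale for the joint count observed. Departures of a library that many genes share, as in NSC 3, were not simulated. The covariance was 3.534 against 0.157 simulated, a difference of 3.377. With 3 NSC libraries the controls cannot be split, so part of the excess may come from the shared controls. The joint count of 3139 was 1546 without NSC 1, 1636 without NSC 5, 1717 without NF1 1 and 6062 without NF1 2. Among the genes higher in both were Rnf183 (11.75 ± 4.83 CPM in LTR, 12.59 ± 2.24 in the libraries labelled NF1), the cytokine receptor gene Flt3 (36.09 ± 14.7 and 35.46 ± 10.8 CPM against 0.063 ± 0.0871 in NSC) and the acetylcholine receptor gene Chrna1 (27.42 ± 6.4 and 19.15 ± 3.73 CPM). Without NSC 3 the log2 change of Flt3 moved from 8.89 to 11.15 in LTR and from 8.87 to 11.1 in the libraries labelled NF1, and that of Chrna1 from 7.21 to 9.03 and from 6.7 to 8.49. Among those lower in both were Thy1 (63.58 ± 12.5 CPM in NSC, none in LTR, 0.064 ± 0.111 in the libraries labelled NF1), at -9.89 in the latter and -9.28 without NF1 1, with no count in NF1 1 or NF1 3. The 2 genes called in opposite directions were Pitx3 (2.88 in LTR and -2.65 in the libraries labelled NF1, adjusted p = 0.019 and 0.0476) and Rps6ka6, a kinase of the RSK family (1.05 and -0.84, adjusted p = 0.00627 and 0.0212). Rps6ka6 measured 62.6 to 69.5 CPM in LTR, 16.4 to 18.5 CPM in the libraries labelled NF1, and 25.5 to 40.8 CPM in NSC. Pitx3 was low, at 0.847 to 1.1 CPM in NSC and 2.91, 15.1 and 3.07 CPM in LTR 1, 2 and 3. In NF1 1, 2 and 3 it measured 0.174, 0.032 and 0.239 CPM, near or below the floor of 3 counts.

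The tumour groups were then compared with each other, by the same edgeR test. No gene passed after adjustment, with 1596 genes at an unadjusted p under 0.05 and 0.122 as the smallest adjusted p. DESeq2 called 335 genes (196 higher and 139 lower in the libraries labelled NF1) and limma-voom 1, Lhx1 (adjusted p = 0.0262), which had no count in any library labelled NF1 and 8 to 24 CPM in LTR. Without NF1 2 edgeR called 34 genes, and without NSC 3 it called 1, Rps6ka6 (-1.92, adjusted p = 0.0467). Libraries of the groups did not overlap for 1955 genes (12.5%, chance 10%). An effect that passed against NSC in one line and not in the other, such as Cdk4 or Hras, is therefore not shown to differ between them. Of the 29 lists, 20 were not called (camera adjusted p from 0.0803 to 0.971), and no member of any list passed by edgeR adjusted over all genes. Adjusted over the list alone, 3 neural stem cell markers were higher and 2 lower, and 4 oligodendrocyte lineage markers were higher. Neuronal markers had 3 higher and 1 lower, matrix proteases 2 and 1, and Notch and imprinted genes 1 and 1 each. Other guidance cues, mural cell and fibroblast markers, EMT genes, and glycolysis and hypoxia had 1 lower each, and the remaining lists none. Camera called 9 lists, each with an adjusted p of 0.824 with an estimated correlation. Lower in the libraries labelled NF1 were cytokinesis (adjusted p = 0.00579), G1/S genes (6.94e-05), G2/M genes (8.13e-05), mural cell and fibroblast markers (0.00183), cholesterol synthesis (0.00155) and Hox genes (0.0201). Higher were astrocyte markers (0.00288), oligodendrocyte lineage markers (0.00183) and mitochondrially encoded mRNAs (4.08e-05). Without NF1 2 only the last of these was still called (adjusted p = 0.000985), and imprinted genes were called lower (median -0.9, adjusted p = 0.014). Medians of mural cell and fibroblast markers, cholesterol synthesis and Hox genes then stayed similar (-1.42, -0.2 and -0.59, from -1.12, -0.2 and -0.61). Those of astrocyte and oligodendrocyte lineage markers shrank to 0.22 and 0.43. Mitochondrial genes held 1.23%, 0.73% and 1.59% of the counts in LTR 1 to 3, and 1.32%, 2.59% and 2.39% in NF1 1 to 3. NF1 1 thus lay within the LTR range. By fry none of the 9 was called (0.634 each). Mural cell and fibroblast markers were not called without LTR 2 (0.0925), NF1 1 (0.108) or NF1 3 (0.105), oligodendrocyte lineage markers without LTR 1 (0.0621), and Hox genes without LTR 1 (0.12) or on ranks (0.0596). Other lists not called with all libraries were called without NF1 3: guidance cues (0.0062), p53 targets (0.0146), neural stem cell markers (0.0138), integrins and basement membrane (0.0146), matrix proteases and inhibitors (0.000942) and the Notch pathway (0.00343). Without NF1 1 the p53 targets (0.0223), proteases (0.0215) and Notch pathway (0.0494) were called, and without LTR 2 the stem cell markers (0.0432) and mesenchymal glioma genes (0.0461). Without a low-count filter the stem cell, protease and Notch lists were called (0.0405 each), and under the filter of 10 CPM the stem cell (0.0318) and Notch (0.00833) lists.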

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

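Of the tests in this part, those of NSC cells in NF1 2, of a library without the labelled changes, of the sequencing lane, of fibroblasts, of mural cells and of both GC versions were chosen only after the results were seen.

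A difference between the tumour groups, tested with camera, marked 9 gene lists in the libraries labelled NF1 against LTR, given here as median log2 difference. Cytokinesis was at -0.3 (adjusted p = 0.00579), G1/S genes at -0.29 (6.94e-05) and G2/M genes at -0.28 (8.13e-05). Astrocyte markers were at 1.61 (0.00288), or 1.13 with the 2 members at 0 in a line set at their bound, and oligodendrocyte lineage markers at 1.26 (0.00183). Mural cell and fibroblast markers were at -1.12 (0.00183), cholesterol synthesis at -0.2 (0.00155), Hox genes at -0.61 (0.0201) and mitochondrially encoded mRNAs at 0.91 (4.08e-05). With an estimated correlation each adjusted p was 0.824. Without NF1 2 the first 4 had an adjusted p of 0.7, and only mitochondrially encoded mRNAs were still called (0.000985). The medians of the first 4 were then -0.03, 0.01, 0.08 and 0.22, and that of oligodendrocyte lineage markers 0.43. Those of mural cell and fibroblast markers (-1.42), cholesterol synthesis (-0.2) and Hox genes (-0.59) stayed similar. For these lists the lost call does not show that NF1 2 made the difference.

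NF1 2 stands apart from NF1 1 and NF1 3. If NSC cells mixed into NF1 2 were the whole cause, its genes would lie between NSC and the other NF1 libraries, yet 159 genes of at least 10 CPM lay above 2 times the highest of the other 8 libraries, against 4 in NF1 1, 0 in NF1 3 and 116 in NSC 3. Over 88 genes nearly absent from the other tumour libraries, its median was 6.59% of the NSC level (0.782 to 28.1 for the middle 80%), so a smaller share is possible. GC content and transcript length accounted for 6.69% of the variance of its log2 ratio to the other NF1 libraries, which argues against such a trend. Its Cdk4 was 1.06 times the NSC mean. Cdk4 was also higher than NSC in LTR, whose label has no CDK4, so its level does not read the label. Nf1 of NF1 2, at 97.2 CPM, lay near the NSC mean of 102 ± 17.1, against 59 and 40.1 CPM in NF1 1 and NF1 3. Cells without the labelled changes would give both genes at the NSC level, as seen, but this prediction was written after the values were known. These levels therefore cannot decide whether NF1 2 holds cells without the labelled changes. The 6.59% over the 88 genes argues against NF1 2 being NSC cells alone. No biological explanation was tested.

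The many genes changed against NSC could come from the sequencing lane, which is the same for all tumour libraries. Over 4470 genes changed in LTR, on a scale of 0 for LTR to 1 for NSC, NF1 2 lay at 0.54, NF1 1 at 0.12 and NF1 3 at -0.03, which shows that libraries of one lane differ and leaves a lane effect on other genes open. With each library's GC trend (range 0.34 on the log2 scale) taken out and centred, 5668 genes changed in LTR (2344 higher, 3324 lower) and 3657 in the libraries labelled NF1, which argues against a GC trend as the cause. Not centred, 6828 (4340 higher, 2488 lower) and 5055 changed, and NF1 against LTR stayed at 0 either way. The transformation that the labels name is a candidate explanation that the design cannot separate from lane.

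Col1a1, Acta2 and Tagln were high in NSC 1 (487.1, 796.4 and 469.7 CPM) and NSC 5 (621.2, 917.9 and 594.1 CPM) and lower in NSC 3 (16.51, 165 and 95.58 CPM). Fibroblasts in the cultures would bring Col3a1, Dcn and Lum, but these together were 0.391% of Col1a1 in NSC 1 and 0.212% in NSC 5 (1.97% in NSC 3), which argues against fibroblasts as the source. Mural cells would bring the other mural genes of the list, but Pdgfrb, Rgs5, Anpep, Myh11, Kcnj8, Abcc9 and Vtn together were 1.72% of Acta2 in NSC 1 and 1.71% in NSC 5. Most of that was Pdgfrb, which moved with Acta2 (13.05 CPM in NSC 1, 15.02 in NSC 5 and 2.671 in NSC 3). The test therefore cannot decide on mural cells that express Pdgfrb without the others. Those others lay at 0 to 0.5095 CPM in NSC 1 and NSC 5, which argues only against mural cells with their transcripts. No biological explanation was tested.

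Regrouping the libraries gave chance counts. With 10 splits of 6 libraries a share under 0.05 is impossible. For genes changed, 1 of 10 splits gave a count as large in LTR against NSC (5634, highest other 0), 1 in NF1 against NSC (3631, highest other 0) and 10 in NF1 against LTR (0, highest other 1). For list calls it was 3 of 10 (16, highest other 18), 1 (18, highest other 15) and 7 (9, highest other 17), so that chance regrouping could give as many list calls in LTR against NSC and between the tumour groups. For genes changed in both tumour groups, 2 of 100 splits of the 9 libraries gave as many as 3139 (highest other 3214). Only splits that kept NSC 1, NSC 3 and NSC 5 together gave any joint call, with 2886 and 3214 under mixed tumour groups. Few splits do so, which set a small share in advance, so the test cannot decide on chance.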

How the results depend on the processing

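Leaving out NF1 2 and NSC 3 together, and both GC versions, were chosen only after the results were seen. For genes changed, LTR against NSC gave 5634, and 3477 with the replicate number as a block, 2024 against a 2-fold threshold (glmTreat) and 3281 to 7640 with 1 library left out. NF1 against NSC gave 3631, and 2103 with the filter of 10 CPM, 1942 with the block, 7485 without NF1 2 and NSC 3, 1233 by glmTreat and 1752 to 6900 with 1 library left out. NF1 against LTR gave 0, and 52 without a filter, 335 by DESeq2, 1 by limma-voom, 104 without both libraries and 0 to 34 with 1 left out. Genes changed in both lines numbered 3139, and 1860 with the filter of 10 CPM, 1765 with the block, 6587 without both libraries and 1546 to 6062 with 1 left out. List calls numbered 16, 18 and 9, and 0 in each comparison with an estimated correlation. In NF1 against LTR they were 0 by fry, 3 without both libraries and 2 to 14 with 1 left out. The cause was not tested. Reversed were G1/S and G2/M genes in NF1 against LTR (adjusted p 0.678 each without both libraries, 1.61e-10 to 0.7 and 1.35e-10 to 0.7 with 1 left out, 1.61e-10 to 0.824 and 1.35e-10 to 0.824 over all alternatives), Uty in NF1 against NSC (-1.13 without both libraries) and Epha7 in NF1 against NSC (-2.25 to 0.73 with 1 left out), and the cause was not tested. The correlation of fold changes, 0.888, stayed within 0.782 to 0.932. In the block fit, 29.5% and 28.1% of the calls against NSC were higher, and in NF1 against NSC the G1/S (adjusted p = 0.00878) and G2/M genes (0.00832) were called and interferon-stimulated genes (0.248) and mitochondrially encoded mRNAs (0.0553) were not, while Eph receptors and ephrins were called in LTR (0.0485) and NF1 (0.0429) against NSC. The labels do not say that the numbers pair the cultures. Deviations of LTR and NF1 cultures 1, 2 and 3 correlated at 0.121, -0.029 and -0.185. Those of NSC and LTR correlated at 0.093 and -0.051, and those of NSC and NF1 at -0.076 and 0.038. With 3 cultures per group the deviations depend on each other, so these values cannot exclude pairing. Over all alternatives of the named genes, 6233 results kept their side of the threshold, 250 lost it, 64 gained it and 2 reversed, and of the list results 1483, 106, 48 and 4. Depth limits genes near the floor of 3 counts, 0.0541 to 0.114 CPM. Whether the 29 Hox genes with too few counts were unexpressed or missed at this depth was not tested.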

Other observations

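In this part, the look at the genes highest in NF1 2 and the genes named from the fit without it were chosen only after the results were seen. Among the genes that stood highest in NF1 2, picked after the values were seen, Spp1 measured 9375 CPM there against 3405 and 3644 in NF1 1 and NF1 3, the matrix glycoprotein gene Tnc 5973 against 583 and 397, and the BMP antagonist gene Grem1 1115 against 39 and 19.7. The chaperone genes Hyou1 and Pdia4 of the endoplasmic reticulum measured 733 and 855 CPM against 225 to 323 in NF1 1 and NF1 3, the oxidative stress genes Hmox1 and Slc7a11 286 and 295 against 38.5 to 61, and the cytokine gene Il11 422 against 16.4 and 24.9.

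Leaving out NF1 2, edgeR called 34 genes between the tumour groups, 7 higher and 27 lower in the libraries labelled NF1. The ones named here were chosen after the values were seen. Eif2ak4, an amino acid sensing kinase gene, was higher (3.7, adjusted p = 0.00361), and Itpripl2 (-6.94, 0.00753), the adhesion gene Nfasc (-3.74, 0.00753), Zfp521 (-3.91, 0.0199), the guidance receptor gene Robo1 (-3.31, 0.0216) and Egfr (-2.14, 0.0244) were lower. Nkx2-2 was higher (3.41, 0.0285). These calls rest on NF1 1 and NF1 3. In NF1 2, Nfasc (17.06 CPM) and Zfp521 (12.9 CPM) lay above every LTR library, against the direction called. Eif2ak4 measured 39.15 CPM there, against 297.2 and 441 in NF1 1 and NF1 3 and 22.93 to 32.7 in LTR. Itpripl2, Robo1, Egfr and Nkx2-2 kept their direction in NF1 2 (3.169, 4.77, 5.314 and 2.913 CPM).

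Every library expressed Xist (36.7 to 216 CPM), which overlaps Tsix, and the Y-linked genes Ddx3y (13.9 to 65.9 CPM), Eif2s3y (20.1 to 94.4), Uty (5.9 to 27.6) and Kdm5d (1.07 to 22.1). Col3a1 measured 152.2 CPM in LTR 1, against 30.4 in LTR 2 and 16.36 in LTR 3.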
